A study of Mus musculus with 12 samples.

How the data were processed

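RNA was measured in tibialis anterior muscle of 4-month-old mdx mice, a strain that lacks functional dystrophin and serves as a model of Duchenne muscular dystrophy. Muscles had been injected with cardiotoxin, a snake venom toxin that destroys muscle fibres and sets off regeneration, together with an inhibitor of the microRNA miR-106b or with a scrambled control inhibitor. They were collected 3 or 7 days later. The 12 libraries form 4 groups of 3 animals: scrambled at day 3, anti-miR-106b at day 3, scrambled at day 7 and anti-miR-106b at day 7. The study's description gives 3 animals per group, but not whether an animal gave a muscle to more than 1 group, and the libraries were treated as independent. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with an Illumina TruSeq RNA kit. The study's description gives the later time once as day 5, while the label of every library says 3 or 7, so 3 and 7 were used.

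The deposited values are log2 CPM, reads of a gene scaled to the size of its library, for 28116 gene symbols. Per the submitters' processing notes, FastQC 0.72, Trim Galore 0.4.3.1, STAR, featureCounts, edgeR 3.20.9 and limma 3.34.9 were used on the mouse genome build mm10. The notes do not give their order or settings, nor whether reads were counted by strand, so reads of a gene and of an antisense partner cannot be told apart. Genes with near-identical copies, such as Rps10 with its pseudogenes, are uncertain for the same reason. The values themselves show what was done to them. After removal of the logarithm every column has equal steps, which gives back the reads of each gene, whole numbers within 0.001, and the library size that the authors used. A prior of 0.25 reads on average had been added, in proportion to library size. The library sizes had been scaled by factors whose group means were 1.12 ± 0.03, 1.28 ± 0.03, 0.845 ± 0.037 and 0.828 ± 0.022 (SD, n = 3), in the order of groups above. Every symbol had a read in at least 3 libraries.

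The recovered totals were 28,900,000 to 42,800,000 reads per library, and 22518 to 24620 symbols had at least 1 read. A single read equals 0.0213 to 0.0356 CPM, so a level of 1 CPM rests on 28.1 to 46.9 reads. Intervals and floors of low counts cover counting error only, since the reads carry no molecular identifiers.

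The deposited log2 values were analysed with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 libraries and a prior variance that follows expression level (8 residual and 5.59 prior degrees of freedom). Genes were tested when they reached 1 CPM in at least 3 of the 12 libraries, which kept 14063. p values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p below 0.05. Tests were two-sided. An exact permutation test of 3 against 3 animals cannot go below 0.1, so single genes were tested with limma only. The comparisons were anti-miR-106b against scrambled at day 3, at day 7 and as the mean of both days, the change of that effect from day 3 to day 7, and day 7 against day 3 within each arm. Replicate numbers were not treated as pairs: residuals of libraries with the same number on the same day had correlations across genes of -0.04 to 0.14.

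Of 36 gene lists written down for muscle, immune, stromal, vascular, nerve, cell cycle and metabolic functions and for targets of miR-106b reported in the literature, 33 had at least 5 kept genes and were tested. They were tested with camera in limma with a preset correlation of 0.01 between genes, again with the correlation estimated from the residuals, and with fry, which asks whether a list's own genes move. Calls made with the preset correlation were lost with the estimated correlation in every comparison. For an unbiased look at targets, the longest annotated 3′ UTR of each gene was searched for GCACTTTA, the 8-base match to bases 2 to 8 of miR-106b-5p followed by A. Gene positions and UTRs came from GENCODE M21 (GRCm38, the same assembly as mm10), which held 27912 of the 28116 symbols. Among kept genes 12921 had a 3′ UTR, 568 had the site and 7547 had no match even to its 6-base core. The shift was the median of the genes with the site minus that of the genes without a match. The camera test instead set the genes with the site against all other kept genes. The search was repeated with 100 shuffled sites.

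Genes named in the text followed a rule: the 12 with the smallest p in each direction among passing genes with an ordinary symbol (for day 7 against day 3, the 8 with the largest fold change in each direction whose groups do not overlap), a fixed set of 12 genes, and up to 4 members per list with the smallest p. Of the fixed set, those reported are Mcm7, Myf5, Cdkn1a, E2f1, Tgfbr2, Pax7, Myod1, Myog, Myh3, Dmd and Utrn. Day 3 and day 7 genes of the first part are named except for some that are not reported here, and the others are examples. Groups, comparisons, lists, this rule and most alternatives were set before the data were examined. The alternatives were other thresholds and filters, larger added constants, median centring, quantile normalization, other variance priors, library weights, fits on the compared groups, replicate blocks and each library left out. Total-count scaling, median-of-ratios scaling and voom weights on the recovered reads were added after the values had been seen, as was leaving out scrambled day 7 replicate 1 and anti-miR-106b day 7 replicate 2 together.

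The fit was tested on simulated reads with the real library sizes and 50 genes changed per fold size. Both arms started from the scrambled means of their day. Genes were drawn independently, so the rates do not cover structure shared among libraries or many genes changing together. Each gene had the same spread in every group, estimated from all 12 libraries. Real libraries of a group differed more at day 7. The chi-square per gene between the reads of a pair was 12.8 to 52.8 there, against 4.49 to 15.6 at day 3. The rates thus do not cover a larger spread at day 7. At day 3 the fit recovered 22% of 1.25-fold, 68% of 1.5-fold, 82% of 2-fold and 96% of 4-fold changes, and called 1 of 13843 unchanged genes. At day 7 the shares were 20%, 66%, 82% and 98%, with 9 unchanged genes called. For the mean of both days they were 48%, 90%, 94% and 98%, with 4 unchanged genes called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.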

Results

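The data are gene expression levels of injured and regenerating mdx muscle in 12 libraries, 3 animals for each combination of inhibitor and day. Total reads were 32,700,000 ± 934,000 for scrambled day 3, 33,800,000 ± 4,430,000 for anti-miR-106b day 3, 39,600,000 ± 3,750,000 for scrambled day 7 and 35,900,000 ± 2,220,000 for anti-miR-106b day 7 (SD, n = 3 each). The question was how inhibition of miR-106b during regeneration changes the muscle's expression profile. The table has no entry for Mir106b, nor for Mir93 and Mir25 of the same cluster, so the inhibition itself was not measured here. The cluster lies within the gene Mcm7, a subunit of the replicative helicase (chromosome 5, 138164583 to 138172422, minus strand, GRCm38). Mcm7 was at 4.50 ± 0.09, 4.93 ± 0.14, 3.66 ± 0.14 and 3.71 ± 0.02 log2 CPM in scrambled day 3, anti-miR-106b day 3, scrambled day 7 and anti-miR-106b day 7 (SD, n = 3). An inhibitor that binds the mature microRNA need not alter this host transcript, so these levels do not check the labels.

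Time after injury separated the libraries most. Principal component 1 held 87.7% of the variance and placed scrambled day 3 at -45.1 ± 5.39, anti-miR-106b day 3 at -81.8 ± 1.42, scrambled day 7 at 63.5 ± 14.4 and anti-miR-106b day 7 at 63.4 ± 12.3 (SD, n = 3). The day 3 arms stood apart on it and the day 7 arms overlapped. Mitochondrial reads made up 7.64 ± 0.109% and 4.81 ± 0.0186% of all reads in the scrambled and anti-miR-106b arms at day 3, and 9.59 ± 1.248% and 10.2 ± 0.391% at day 7. The 10 most abundant genes of each library took 17.3 ± 0.750%, 12.0 ± 0.181%, 23.1 ± 0.342% and 22.2 ± 0.287% of its reads, in the same order of groups.

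**Figure D1:**
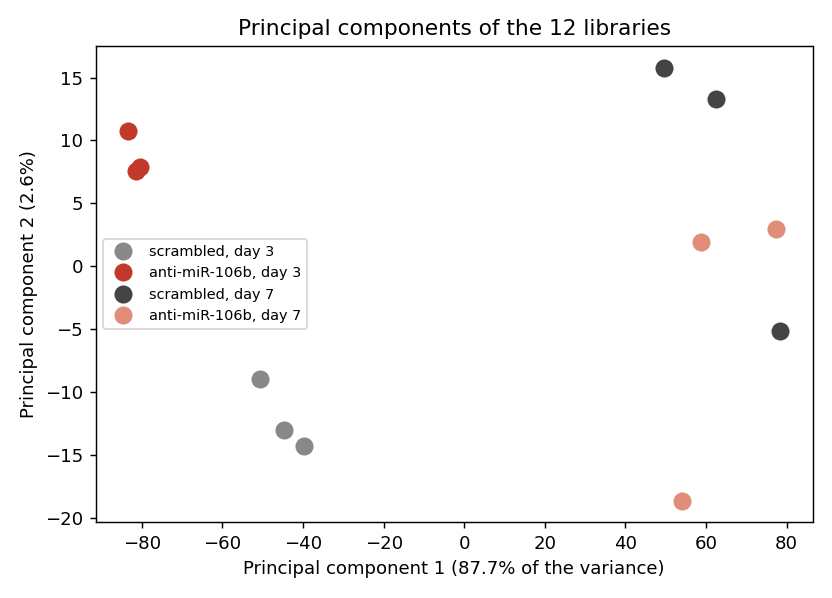
Principal components 1 and 2 of the log2 CPM values of the 14063 kept genes, as scores without units, with each point a library coloured by group. Component 1 (87.7% of the variance) separates day 3 on the left from day 7 on the right, and at day 3 the anti-miR-106b libraries lie further left than the scrambled ones.

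At day 3, lists of interferon-induced, macrophage, matrix and cell division genes were higher in muscles given anti-miR-106b than in scrambled controls. Lists of mature fibre and mitochondrial genes were lower. These are calls of camera with the preset correlation, and none of them held with an estimated one. Uba7, the ubiquitin-activating enzyme of ISG15 and an interferon-induced gene (chromosome 9, 107975505 to 107984060, plus strand), rose from 4.83 ± 0.03 to 5.66 ± 0.13 log2 CPM (SD, n = 3), a log2 fold change of 0.83 ± 0.09 (SE). Sec14l5 (chromosome 16, 5147109 to 5187271, plus strand) had the smallest p among lower genes and fell from 5.76 ± 0.02 to 4.73 ± 0.04 log2 CPM, a change of -1.03 ± 0.06. In limma 5022 of 14063 genes passed, 2296 higher and 2726 lower with anti-miR-106b. Most changes were moderate: the median size among passing genes was 0.45 on the log2 scale, and 72 higher and 137 lower genes changed at least 2-fold. The 3 animals of each arm did not overlap in 60.5% of all tested genes, against 10% by chance.

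The genes with the smallest p among those that rose included, beside Uba7, the class I histocompatibility gene H2-T22 (log2 fold change 0.68). Matrix and mesenchymal genes were periostin Postn (0.82), elastin Eln (1.14), Lrrc15 (0.86) and Olfml3 (0.80). The others were the adaptor Dok1 (0.93), the opioid growth factor receptor Ogfr (0.70), the purine nucleoside phosphorylase Pnp (0.79), the aminopeptidase Rnpep (0.61) and the lysosomal cholesterol transfer protein Npc2 (0.69). Among those that fell were genes of glycogen metabolism, Ppp1r3a (-1.03), the glycogen-targeting subunit of a phosphatase, and Phkg1 (-1.05), the catalytic subunit of muscle phosphorylase kinase. Cacna2d1 (-0.80), a calcium channel subunit of muscle, and Ano5 (-0.75), a gene of limb-girdle muscular dystrophy, fell as well. Nctc1 (-0.90), Carnmt1 (-0.87), Pla2g4e (-0.90), Exd2 (-0.77), Tmtc1 (-0.75), Tpbgl (-0.79) and the mitochondrial transfer RNA mt-Tp (-0.89) complete this set. Adjusted p values of these genes in limma ran from 1.94e-06 for Sec14l5 to 4.44e-05 for Npc2.

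Interferon response genes rose most evenly. Of 22 measured members 20 rose and none fell, with a median log2 fold change of 0.83, and 22 passed when adjusted over the list alone. Isg15 (1.20 ± 0.18 SE) and Ifit3 (1.07 ± 0.13) are examples. Macrophage markers had 12 of 18 higher and a median of 0.67 (13 higher and 1 lower adjusted over the list alone), with Aif1 at 1.11 ± 0.20 and the complement subunit C1qa at 0.77 ± 0.17. Extracellular matrix genes had 12 of 22 higher, a median of 0.38 and 13 adjusted over the list alone. Among them were tenascin C Tnc (1.11 ± 0.13) and the collagen crosslinking enzyme Lox (0.62 ± 0.09). The camera adjusted p was 5.99e-11 for interferon, 1.29e-04 for macrophage and 1.92e-05 for matrix genes. With an estimated correlation the adjusted p was 0.446, 0.622 and 0.552.

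Genes of cell division and of young fibres were also higher as lists in camera with the preset correlation, with a part of their members passing. DNA replication genes had 8 of 20 higher (10 adjusted over the list alone) and a median of 0.41, with Tyms at 0.73 ± 0.17 and Gins2 at 0.81 ± 0.22. All 20 mitosis genes had positive values and 4 passed (also 4 over the list alone), with a median of 0.49 and Birc5, a survivin of dividing cells, at 0.79 ± 0.24. Mcm7, a DNA replication member, rose by 0.43 ± 0.09 (adjusted p = 0.00246). Of 15 genes of embryonic and neonatal fibres 6 rose, by either count, with a median of 0.59. Examples are the acetylcholine receptor subunit Chrnd (0.79 ± 0.18) and the adhesion molecule Ncam1 (0.60 ± 0.16). Embryonic myosin Myh3 had 0.72 ± 0.28 and did not pass (adjusted p = 0.0628), but passed with library weights (4.10e-04), quantile normalization (0.0109), total-count scaling (0.0226), 5 CPM added (0.0375), the day 3 groups alone (1.12e-05), 2 day 7 libraries left out (0.00304), and without scrambled day 7 replicate 3 (0.0361) or anti-miR-106b day 7 replicate 1 (0.0427) or 2 (0.00678). Of 11 satellite cell genes 6 rose and the median was 0.21, with Cdh15 at 0.61 ± 0.07 and the Notch target Heyl at 0.47 ± 0.10 (6 higher and 1 lower adjusted over the list alone). Pax7, the satellite cell transcription factor, had 0.21 ± 0.12 (adjusted p = 0.187, but 0.0335 under total-count scaling and 0.00254 with library weights), and its fold was 0.11 without scrambled day 3 replicate 3. Of 8 tendon genes 2 rose (also 2 over the list alone), Scx (0.70 ± 0.10) and Comp (0.60 ± 0.15), and the median was 0.28 (0.18 without scrambled day 3 replicate 2). The camera adjusted p was 3.16e-04 for DNA replication, 0.00362 for mitosis, 0.00216 for regenerating fibre and 0.0461 for both satellite cell and tendon genes. It was 0.622 for each of these 5 lists with an estimated correlation. The call of Birc5 was lost without scrambled day 3 replicate 2 (adjusted p = 0.0853), replicate 3 (0.0540) or anti-miR-106b day 3 replicate 2 (0.0691), and that of Gins2 without scrambled day 3 replicate 3 (0.0522) or anti-miR-106b day 3 replicate 2 (0.0585).

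Mature fibre and energy metabolism genes fell together. All 24 oxidative phosphorylation genes fell, with a median of -0.54 and the same 24 adjusted over the list alone. Ndufs1 of complex I had -0.68 ± 0.07 and Uqcrfs1 of complex III had -0.71 ± 0.08. Of 22 mature fast fibre genes 21 fell by either count (median -0.73), among them glycogen phosphorylase Pygm (-0.86 ± 0.10) and the AMP deaminase Ampd1 (-0.79 ± 0.09). Of 16 fatty acid oxidation genes 13 fell (15 over the list alone, median -0.47), with the coactivator Ppargc1a at -0.70 ± 0.12 and the acyl-CoA synthetase Acsl1 at -0.60 ± 0.09. Of 9 mitochondrially encoded genes 8 fell (9 over the list alone, median -0.89), such as mt-Nd5 (-0.92 ± 0.11) and mt-Nd2 (-0.95 ± 0.14). Hypoxia and glycolysis genes were mixed, with 9 of 14 lower and 2 higher (10 and 3 adjusted over the list alone, median -0.52). Lactate dehydrogenase Ldha (-0.73 ± 0.10) and the vascular growth factor Vegfa (-0.91 ± 0.13) were lower. The camera adjusted p was 1.09e-13, 5.99e-11, 2.90e-06, 1.14e-05 and 0.00560 for these 5 lists in turn, and with an estimated correlation the adjusted p was 0.446 for the leading 4 and 0.622 for hypoxia and glycolysis.

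Of 13 dystrophin complex genes 8 fell, by either count, with a median of -0.36 (camera adjusted p = 5.68e-04, and an adjusted p of 0.446 with an estimated correlation). Dmd itself (chromosome X, 82948870 to 85206141, plus strand), whose transcript is still made in mdx muscle, went from 4.11 ± 0.06 to 3.59 ± 0.04 log2 CPM (SD, n = 3), a change of -0.52 ± 0.08 (SE; adjusted p = 3.96e-04). The dystrobrevin Dtna had -0.49 ± 0.05. Utrn, the dystrophin homologue, had -0.01 ± 0.08 (adjusted p = 0.939).

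The remaining lists did not pass at day 3. Myoblast and early differentiation genes had 7 of 14 higher and 1 lower (8 and 2 adjusted over the list alone), a median of 0.53 and an adjusted p of 0.1002. The myogenic regulators Myod1 (0.50 ± 0.13, adjusted p = 0.0112) and Myog (0.74 ± 0.22, 0.0170) rose within it. Without scrambled day 3 replicate 2 neither passed (0.0549 and 0.0716), nor without anti-miR-106b day 3 replicate 2 (0.0612 and 0.0589). Slow fibre genes had a median of 0.81 with 3 higher and 1 lower of 11 (5 and 1 over the list alone, adjusted p = 0.1002). The slow troponins Tnnt1 (1.05 ± 0.28) and Tnnc1 (1.15 ± 0.29), which developing fibres also make, were among the higher. Endothelial genes had 5 of 12 higher (6 and 1 lower over the list alone), with a median of 0.18 and Eng at 0.60 ± 0.08 (adjusted p of the list = 0.1002). Inflammatory monocyte genes had 2 of 14 higher (1 over the list alone), a median of 0.48 and an adjusted p of 0.1002. Its member Arg1, an enzyme of arginine breakdown, had the largest rise of the genes named here (2.91 ± 0.47, but 2.15 and 1.14 with 1 and 5 CPM added). TGF-beta and BMP genes went both ways, with 7 higher and 4 lower of 20 (7 and 6 over the list alone), a median of 0.00 and an adjusted p of 0.509. Ctgf (0.92 ± 0.15) rose. Schwann cell genes had 1 of 7 lower, by either count, and a median of -0.18 (adjusted p = 0.453).

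No passing list was found among the other cell types and states. The medians at day 3 were 0.65 for T and NK cells (adjusted p = 0.0973), -0.48 for adipocytes (0.0901), 0.63 for erythrocytes (0.120), 0.49 for neutrophils (0.304), -0.07 for mast cells and eosinophils (0.885) and 0.07 for pericytes and smooth muscle (0.722). They were -0.03 for fibroblasts and fibro-adipogenic progenitors, whose mean was positive (0.637), 0.17 for atrophy and denervation (0.141), 0.06 for the neuromuscular junction (0.885), 0.07 for p53 targets and cell cycle arrest (0.509), 0.16 for immediate early genes (0.452) and -0.05 for autophagy and lysosome (0.996).

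Beside these gene groups the share of mitochondrial reads was lower with anti-miR-106b in all 3 animals, as was the share of the 10 most abundant genes. Scaling to total reads, chosen after the values had been seen, put the median of all genes at 0.20 at day 3 and gave 6566 genes, 5189 higher and 1377 lower, so the balance of directions rests on the scaling. It ended the calls of the regenerating fibre (adjusted p = 0.0733), mitosis (0.126), satellite cell (0.0757) and tendon lists (0.145), and quantile normalization ended those of the mitochondrially encoded (0.0524), hypoxia (0.0900), satellite cell (0.0524) and tendon lists (0.0685), while none of the 14 lists changed direction. The satellite cell call was lost as well at 0.5 CPM (0.0744), with 1 or 5 CPM added (0.0588 and 0.0697), library weights (0.0583), voom weights (0.0634), the day 3 groups alone (0.0869) and 2 day 7 libraries left out (0.0626). The tendon call was lost with 1 or 5 CPM added (0.0588 and 0.0773), a prior without trend (0.0672), voom weights (0.0664), the day 3 groups alone (0.0548) and 2 day 7 libraries left out (0.0584). Of single libraries, the satellite cell call was lost without scrambled day 3 replicate 2 (0.0612) or 3 (0.0560), anti-miR-106b day 3 replicate 2 (0.0637), or scrambled day 7 replicate 1 (0.0645) or 3 (0.0589), and the tendon call without scrambled day 3 replicate 2 (0.111), anti-miR-106b day 3 replicate 1 (0.0604), scrambled day 7 replicate 3 (0.0589), or anti-miR-106b day 7 replicate 2 (0.0570) or 3 (0.0529). With library weights 8820 genes passed.

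**Figure D2:**
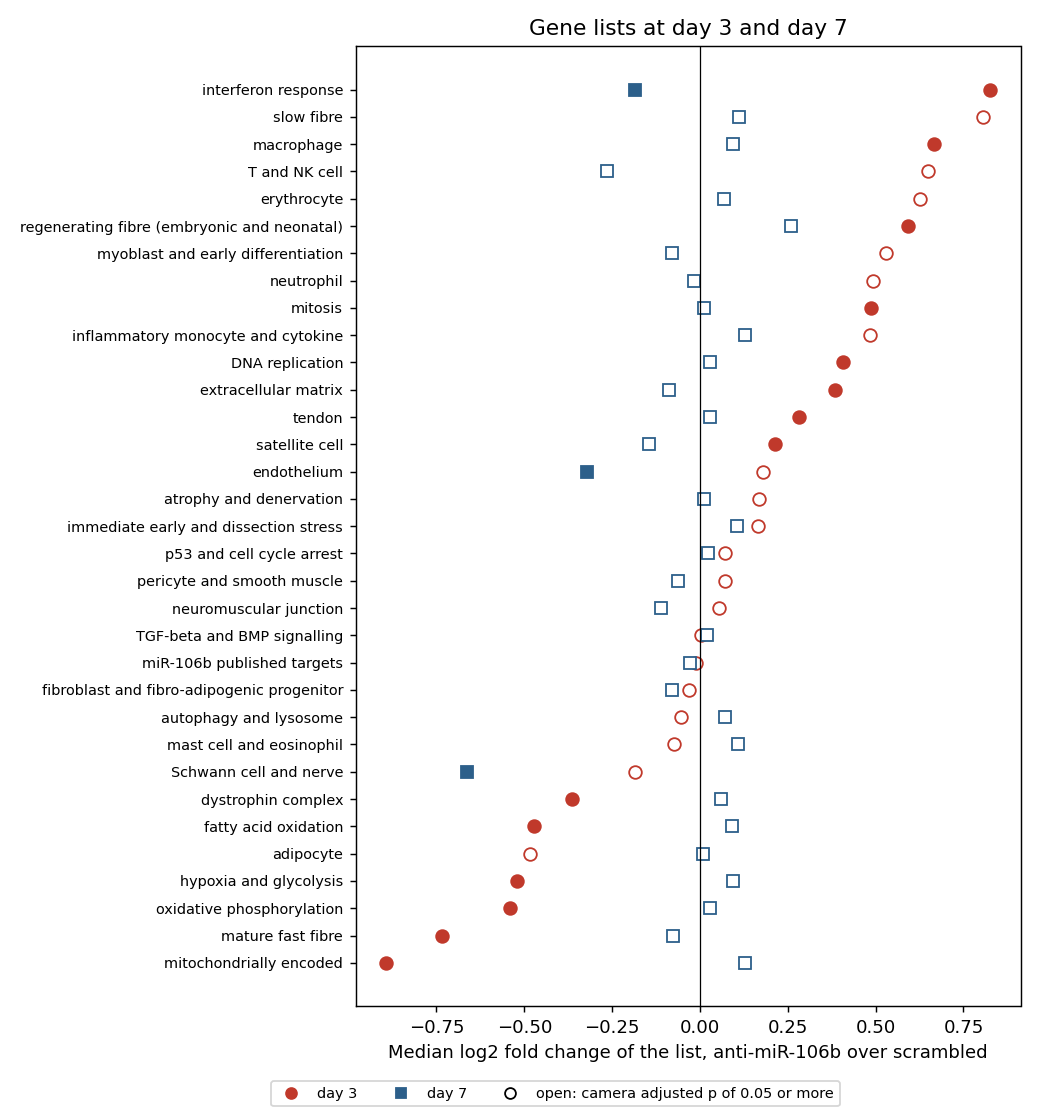
Median log2 fold change of anti-miR-106b over scrambled for the 33 tested gene lists at day 3 (circles) and day 7 (squares), with filled symbols for a camera adjusted p below 0.05. At day 3 the medians run from -0.89 (mitochondrially encoded) to 0.83 (interferon response), while at day 7 the filled squares are interferon response, endothelium and Schwann cell and nerve, all below 0.

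Published targets of miR-106b did not move together at day 3. Of 40 measured, 4 rose and 10 fell, by either count, with a median of -0.01 (camera adjusted p = 0.538). The cell cycle inhibitor Cdkn1a rose by 0.70 ± 0.13 (adjusted p = 0.00130), while the mitochondrial fusion gene Mfn2 (-0.74 ± 0.10) and the lipoprotein receptor Vldlr (-0.98 ± 0.11) fell. Myf5, a myogenic regulator (chromosome 10, 107482908 to 107486134, minus strand), was at 2.27 ± 0.34 and 2.36 ± 0.05 log2 CPM (SD, n = 3), a difference of 0.10 ± 0.23 (SE; adjusted p = 0.760). E2f1 had 0.39 ± 0.15 (0.0553) and Tgfbr2 0.18 ± 0.09 (0.150), and both passed in some alternatives, for example under total-count scaling (0.0101 and 0.00868). The fold of Tgfbr2 was 0.11 without scrambled day 3 replicate 1. Genes with an 8-base seed match in the 3′ UTR had a median of -0.06 against 0.06 for genes with no match, a shift of -0.12, with 53 higher and 147 lower of 568. Against all other kept genes, camera gave p = 0.0209 for the genes with a site, but p = 0.342 with an estimated correlation. Of 100 shuffled sites, 13 gave a shift as low. The genes with a site had longer 3′ UTRs, with a median of 2670 bases against 712.

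At day 7 few single genes differed between the arms. Vessel and nerve genes were lower with anti-miR-106b as lists in camera with the preset correlation, a call not kept with an estimated one. In limma 9 genes passed, 1 higher and 8 lower, and 1580 had an unadjusted p below 0.05 (11.2%). The groups did not overlap in 10.9% of genes, against 10% by chance. The circadian repressor Ciart was higher (log2 fold change 1.39 ± 0.19 SE, adjusted p = 0.0205). Aplnr, the apelin receptor of endothelial cells (chromosome 2, 85136225 to 85139923, plus strand), went from 5.22 to 4.65 log2 CPM, a change of -0.57 ± 0.06 (adjusted p = 0.00651). The protocadherins Pcdh12 (-0.67 ± 0.10), known from endothelium, and Pcdh1 (-0.60 ± 0.09), the adhesion gene Igsf9b (-0.68 ± 0.11) and Ltbp4, a binding protein of latent TGF-beta (-0.46 ± 0.08), were lower too. The other lower genes were Rps10 (-0.98 ± 0.13), whose reads may be shared with pseudogenes, Mir6236 (-1.43 ± 0.20), which lies in sequence resembling ribosomal RNA, and the unnamed Gm25732 (-1.81), which the naming rule left out and was added after its value was seen.

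All 12 endothelial genes had negative values at day 7, with a median of -0.32. None passed over all genes and 10 were lower when adjusted over the list alone. Pecam1 (-0.39 ± 0.07, adjusted p = 0.0540), Cdh5 (-0.42 ± 0.07, 0.0554), Emcn (-0.44 ± 0.09, 0.0704) and Tie1 (-0.37 ± 0.08, 0.0761) are examples, and all 4 passed without scrambled day 7 replicate 1 (0.0221, 0.0152, 0.0468 and 0.0440). All 7 Schwann cell and nerve genes were negative with a median of -0.66, 0 passing over all genes and 4 adjusted over the list alone, among them the myelin genes Prx (-0.74 ± 0.14, adjusted p = 0.0613) and Mbp (-0.66 ± 0.22, 0.285; -0.35 without anti-miR-106b day 7 replicate 2). The camera adjusted p was 1.21e-13 for endothelium and 1.42e-05 for nerve. With an estimated correlation the adjusted p was 0.0759 for both, and fry gave adjusted p values of 0.00903 and 0.00931. Interferon genes had a median of -0.19, with 18 of 22 negative, 0 passing and 1 adjusted over the list alone (camera adjusted p = 0.00201, and an adjusted p of 0.972 with an estimated correlation). Ifi44 had -0.70 ± 0.18 (0.179) and Ifit3 -0.36 ± 0.13 (0.320; -0.23 without anti-miR-106b day 7 replicate 2). The other 30 lists did not pass, including oxidative phosphorylation (median 0.03, adjusted p = 0.900), mature fast fibre (-0.08, 0.156) and macrophage genes (0.09, 0.197). The mitochondrially encoded list had a median of 0.13 and a negative mean (adjusted p = 0.828). Without scrambled day 7 replicate 3 the interferon call was lost (median -0.07, adjusted p = 0.558). The share of ribosomal RNA reads, with Mir6236 counted among them and looked at only after the values had been seen, was 0.0960 ± 0.00929% in the scrambled arm and 0.0434 ± 0.00596% in the anti-miR-106b arm at day 7 (SD, n = 3). At day 3 it was 0.0462 ± 0.00690% and 0.0476 ± 0.0173% in the same order. The scrambled day 7 group thus stood above all other groups, and the anti-miR-106b day 7 group was near the day 3 level.

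Mcm7 (0.05 ± 0.09), Cdkn1a (0.14 ± 0.13), Dmd (0.15 ± 0.08) and Myh3 (0.76 ± 0.28) did not pass at day 7 (adjusted p = 0.894, 0.748, 0.526 and 0.328). Without single libraries Dmd ran from 0.06 (without scrambled day 7 replicate 2) to 0.22 (without replicate 3), Cdkn1a from -0.01 (without anti-miR-106b day 7 replicate 1) to 0.29, and Myh3 from 0.50 (without anti-miR-106b day 7 replicate 1) to 1.18 (without replicate 2, where it passed with an adjusted p of 0.0233). The published targets had a median of -0.03 (adjusted p = 0.537), and genes with the seed match shifted by 0.00. Against all other kept genes, camera gave p = 0.721 for them, and p = 0.880 with an estimated correlation. The number of passing genes at day 7 depended on single libraries. Of the day 7 scrambled libraries, it was 457 without replicate 1, 0 without replicate 2 (1455 with an unadjusted p below 0.05) and 14 without replicate 3, and of the anti-miR-106b ones 2, 70 and 3. The direction changed as well: 58 of the 70 were higher and 12 lower, and of the 457, 216 were higher and 241 lower, and of the 14 without scrambled replicate 3, 8 and 6. Leaving out a day 3 library gave 4, 5 and 3 for scrambled replicates 1, 2 and 3 and 5, 9 and 14 for anti-miR-106b ones. Without both scrambled replicate 1 and anti-miR-106b replicate 2 of day 7, a choice made after the values had been seen, 542 genes passed, 350 higher and 192 lower, and in the fit on the day 7 libraries alone 2 passed. In that fit Ciart, Aplnr, Rps10, Pcdh12, Pcdh1, Igsf9b and Ltbp4 lost their calls (adjusted p from 0.0788 to 0.328). With replicate blocks within day 0 genes passed, so every day 7 call was lost. Pcdh12, Igsf9b and Ltbp4 lost their calls with a filter at 5 CPM (0.0532 each), Mir6236 and Ltbp4 with a prior without trend (0.0661 and 0.0774), and Rps10 and Igsf9b with voom weights (0.0507 each).

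**Figure D3:**
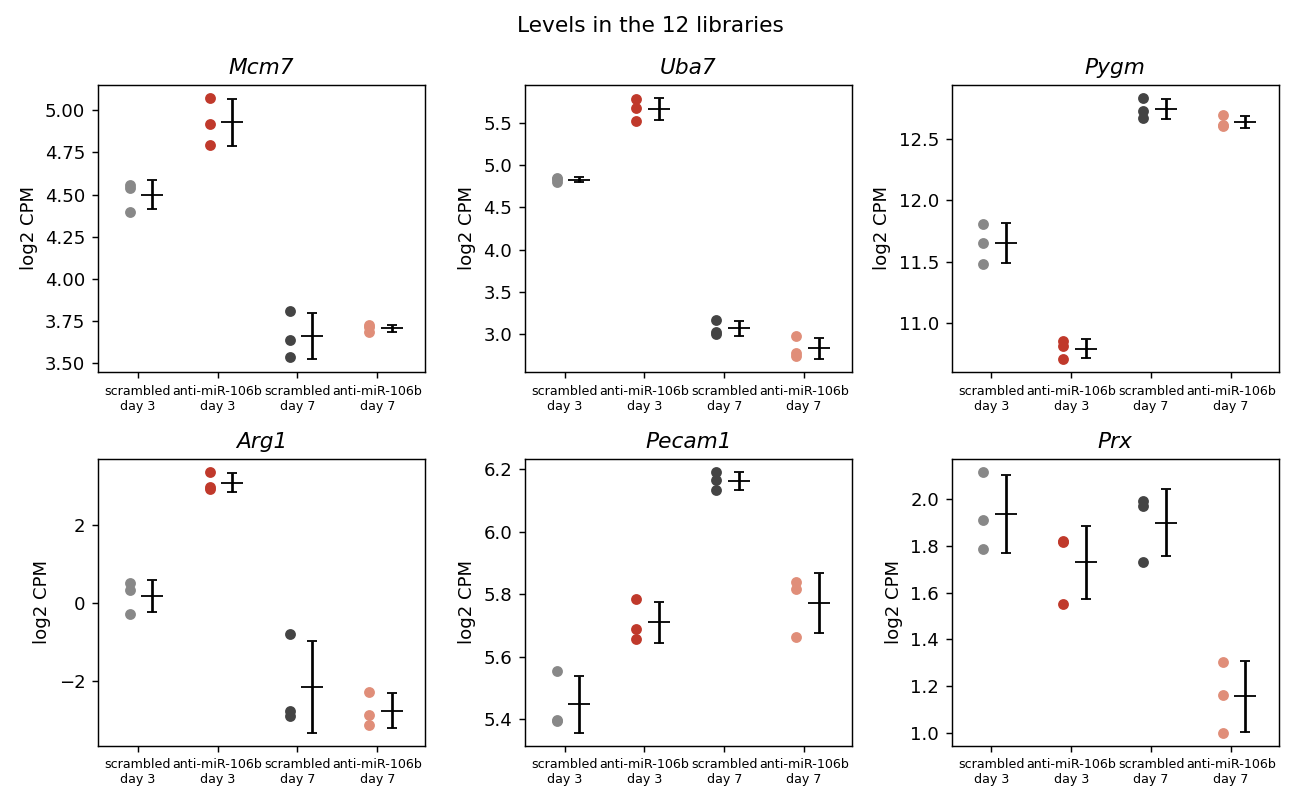
log2 CPM of 6 genes in the 12 libraries, with points for animals and bars for the mean and SD of the 3 animals of each group, on axes that do not start at 0. Uba7 and Arg1 are higher and Pygm is lower with anti-miR-106b at day 3, and the Pecam1 and Prx points of the anti-miR-106b arm lie below those of the scrambled arm at day 7.

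The difference between the arms at day 3 and at day 7 was itself tested. In camera with the preset correlation, the interferon and matrix lists had a more negative effect at day 7 than at day 3. The mature fibre and mitochondrial lists had a more positive one, and no list passed with an estimated correlation. In limma 3134 genes passed, 1858 with a more positive effect at day 7 and 1276 with a more negative effect. Examples of the former are Ppp1r3a (1.26 ± 0.11 SE), Tpbgl (1.01 ± 0.09), Pla2g4e (1.099 ± 0.11), Sec14l5 (0.85 ± 0.09) and Dmd (0.66 ± 0.11). Examples of the latter are Uba7 (-1.07 ± 0.12), Aplnr (-0.90 ± 0.09), Pcdh1 (-1.09 ± 0.13), Myod1 (-0.77 ± 0.19), Cdkn1a (-0.56 ± 0.19) and Mcm7 (-0.38 ± 0.13). Of the 5022 genes of day 3, 2804 passed here as well, and 2766 of these had an effect smaller in size at day 7. Between the arms, 4 genes passed at both days, 1 of them in the same direction.

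Among the lists, 22 of 24 oxidative phosphorylation genes had a more positive effect at day 7 (median 0.55, 24 adjusted over the list alone), as did 16 of 22 mature fast fibre genes (0.69, 19 and 1 in the other direction over the list alone). Effects were more negative at day 7 for 18 of 22 interferon genes (-0.94, 19 over the list alone), 9 of 22 matrix genes (-0.41, 14) and 9 of 12 endothelial genes (-0.50, 9). In all 15 lists passed with camera, 6 up and 9 down, and with an estimated correlation the adjusted p of these lists lay between 0.393 and 0.638. Under total-count scaling 4367 genes passed, 866 up and 3501 down, and the median of all genes was -0.22. Without scrambled day 3 replicate 2 the count was 2063, and with library weights 5334. The call of Mcm7 was lost without any 1 of 10 libraries (adjusted p from 0.0515 to 0.118), all but anti-miR-106b day 3 replicate 3 and scrambled day 7 replicate 2. That of Cdkn1a was lost without any 1 of 8 (0.0659 to 0.119), all but scrambled day 3 replicate 1, scrambled day 7 replicates 1 and 2 and anti-miR-106b day 7 replicate 1. Both calls were also lost with no filter (0.0744 and 0.0630), a prior without trend (0.0608 and 0.0861) and 2 day 7 libraries left out (0.0974 and 0.0813), Mcm7's with median centring (0.0695) and Cdkn1a's with a robust prior (0.0547).

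Averaged over both days, anti-miR-106b went with higher macrophage genes and lower mature fibre genes, mainly through the day 3 difference. The platelet factor Pf4, also made by macrophages (0.63 ± 0.07 SE), the haem oxygenase Hmox1 (0.75 ± 0.10) and Lrrc15 (0.59 ± 0.07) rose, and Sec14l5 (-0.61 ± 0.04) and Nctc1 (-0.50 ± 0.05) fell. Embryonic myosin Myh3 passed in this mean (0.74 ± 0.20, adjusted p = 0.0223), as did Cdkn1a (0.42 ± 0.09, 0.00866), Mcm7 (0.24 ± 0.06, 0.0207) and Dmd (-0.18 ± 0.06, 0.0384). In limma 2624 genes passed, 1143 higher and 1481 lower, and 14 lists passed with camera, 7 up and 7 down. Mature fast fibre (20 of 22 lower, 21 over the list alone, median -0.37), oxidative phosphorylation (23 of 24 lower, 24, -0.27) and macrophage genes (10 of 18 higher, 11, 0.44) were among them. Interferon genes (9 of 22 higher, 13, 0.34) passed too, but their mean holds opposite directions, a median of 0.83 at day 3 and -0.19 at day 7. With an estimated correlation the lowest adjusted p of any list was 0.559. Genes with the seed match shifted by -0.06, and 18 of 100 shuffled sites were as low. Against all other kept genes, camera gave p = 0.0441 for them, and p = 0.404 with an estimated correlation. Under total-count scaling 3509 genes passed, 2707 higher and 802 lower. The count was 1457, 1528 and 1601 without scrambled day 3 replicate 2, scrambled day 3 replicate 3 and anti-miR-106b day 3 replicate 2, and 3991 with library weights. Of the fixed genes, Dmd lost its call without 10 of the 12 libraries in turn (adjusted p from 0.0560 to 0.1) and with total-count scaling (-0.10, 0.263), library weights (-0.11, 0.124), no filter (0.0691), 5 CPM added (0.0561), a prior without trend (0.0534) and 2 day 7 libraries left out (0.0774), Mcm7 without scrambled day 3 replicate 3 (0.0631) or anti-miR-106b day 3 replicate 2 (0.0602), and Myh3 without scrambled day 3 replicate 2 (0.0607), anti-miR-106b day 3 replicate 2 (0.0534), scrambled day 7 replicate 2 (0.0504) or anti-miR-106b day 7 replicate 1 (0.0511) or 3 (0.0574), and with a prior without trend (0.0518) or a robust one (0.0602).

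From day 3 to day 7 in the scrambled arm, inflammatory, proliferative and embryonic genes fell and mature fibre, mitochondrial and endothelial genes rose. Embryonic myosin Myh3 (-4.31 ± 0.28 SE), the fusion peptide Mymx (-4.27 ± 0.30), Myog (-3.20 ± 0.22), the fetal acetylcholine receptor subunit Chrng (-4.53 ± 0.34) and Tnnc1 (-3.48 ± 0.29) fell. So did Cd68 (-2.99 ± 0.18) and Csf1r (-2.42 ± 0.12) of macrophages, Irf7 (-3.51 ± 0.19) and Ifit3 (-2.80 ± 0.13) of the interferon response, Cdt1 (-2.44 ± 0.17) and Ccnb1 (-3.34 ± 0.26) of dividing cells, Postn (-2.12 ± 0.08), Lox (-1.71 ± 0.09) and Cdkn1a (-2.50 ± 0.13). Genes that rose were Pygm (1.102 ± 0.10), Ndufs1 (0.92 ± 0.07), Dmd (0.55 ± 0.08; 0.14 with an adjusted p of 0.191 under total-count scaling), Pecam1 (0.71 ± 0.07) and Cdh5 (0.73 ± 0.07). The largest rises included Mybphl (3.56 ± 0.65), Inmt (2.86 ± 0.40), Mettl21e (1.82 ± 0.18) and Pdk4 (1.67 ± 0.31). That of Mybphl was 2.94 without scrambled day 3 replicate 2 and 4.47 without scrambled day 7 replicate 1, and that of Pygm was 0.21 with quantile normalization. Some of the largest falls ended near 0 reads. Cplx3 went from 81 reads over the group to 0, at least 24.6-fold lower with a floor of 3 reads over the group (lower 95% limit of the ratio 19.6 with the counting error of both groups). Krt31 went from 150 reads to 2 (ratio 68.5, 95% interval 18.6 to 570), Krt33b from 95 to 2 (43.4, 11.7 to 363) and Npy from 77 to 1 (70.3, 12.2 to 2811). The fitted log2 changes of Krt31 and Krt33b (-6.52 and -5.86) were -7.60 and -6.94 without scrambled day 7 replicate 1, and that of Npy (-5.75) was -6.57 without replicate 3.

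In this arm 9587 genes passed in limma, 4624 higher and 4963 lower, and groups did not overlap in 72.4% of genes against 10% by chance. The balance of directions rests on the scaling, with 1519 higher and 8711 lower under total-count scaling and 6397 higher and 3774 lower with median centring. All 22 interferon genes (median -2.54), all 18 macrophage genes (-2.73), all 20 mitosis genes (-2.51), 18 of 20 DNA replication genes (-1.55), 20 of 22 matrix genes (-1.22) and 11 of 15 regenerating fibre genes (-1.79) fell. All 24 oxidative phosphorylation genes (0.91), all 22 mature fast fibre genes (0.89), 15 of 16 fatty acid oxidation genes (0.75) and 10 of 12 endothelial genes (0.69) rose. The counts of these lists were the same when adjusted over the list alone. In all 17 lists passed with camera, 7 up and 10 down, and with an estimated correlation their adjusted p lay between 0.375 and 0.484.

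The anti-miR-106b arm changed in the same directions between the days. Myh3 (-4.27 ± 0.28 SE), Mymx (-5.06 ± 0.30), Myog (-3.89 ± 0.22), Cdkn1a (-3.06 ± 0.13), Aif1 (-3.88 ± 0.20), Csf1r (-2.88 ± 0.12), Ifit3 (-4.24 ± 0.13), Postn (-2.94 ± 0.08) and Arg1 (-5.85 ± 0.47) fell. Pygm (1.86 ± 0.10), Ndufs1 (1.64 ± 0.07), Mfn2 (1.63 ± 0.10) and Dmd (1.21 ± 0.08) rose. Among the largest rises were Slc15a5 (4.41 ± 0.61), Calm4 (3.11 ± 0.57) and the calcium-sensing receptor Casr (2.83 ± 0.17). Among the largest falls were Cd5l (1607 reads to 20), Treml2 (769 to 9) and Tgtp2 (627 to 8), and Dynap went from 253 reads to 3 (ratio 58.1, 95% interval 19.6 to 283). Without anti-miR-106b day 3 replicate 2 the change of Slc15a5 was 3.69. Without anti-miR-106b day 7 replicates 1, 2 and 3 in turn, the fitted log2 changes were -7.36, -7.58 and -5.21 for Treml2 (-6.71 with all), -7.16, -5.02 and -7.18 for Tgtp2 (-6.46) and -8.13, -6.18 and -6.18 for Dynap (-6.83), and without replicate 2 -5.39 for Cd5l (-6.03). Under total-count scaling all changes of genes named here were lower, such as 1.23 for Pygm and 0.58 for Dmd. In limma 11067 genes passed, 5331 higher and 5736 lower (2152 and 9745 under total-count scaling, 6748 and 4650 with median centring), and groups did not overlap in 81.1% of genes. Medians were -3.65 for interferon (22 of 22 lower), -3.22 for macrophage (18 of 18), -2.98 for mitosis (20 of 20), -1.59 for matrix (21 of 22), 1.43 for oxidative phosphorylation (24 of 24 higher) and 1.63 for mature fast fibre genes (21 of 22), with the same counts adjusted over the list alone. Endothelial genes had a median of 0.20 and did not pass (adjusted p = 0.441). In all 16 lists passed, 6 up and 10 down, and with an estimated correlation their adjusted p lay between 0.423 and 0.604.

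**Figure D4:**
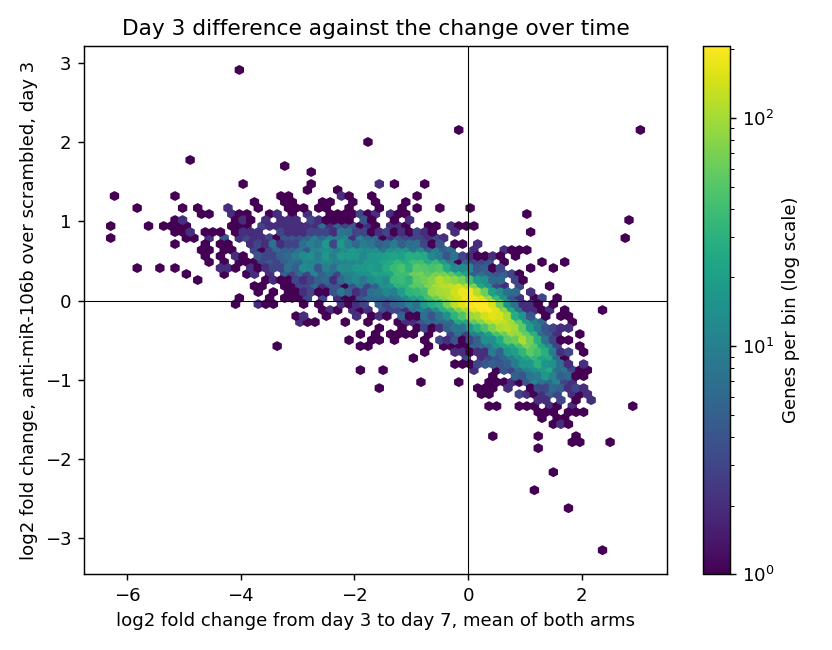
Each tested gene's log2 fold change of anti-miR-106b over scrambled at day 3 against its log2 fold change from day 3 to day 7, averaged over both arms, in hexagonal bins coloured by the number of genes on a log scale. The cloud slopes down (Pearson r = -0.78 across 14063 genes): genes that fell with time were mostly higher with anti-miR-106b at day 3, and genes that rose were mostly lower.

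Across the 14063 genes, the day 3 effect and the mean change from day 3 to day 7 had a Pearson r of -0.78 and a Spearman rho of -0.84. In the other 9 splits of the day 3 libraries, which mix the arms, the size of r was 0.45 to 0.66. Such a split has the arms in unequal numbers on each side. It still holds part of the real difference, so these are not values without a difference. Genes are not independent replicates, so no p is given. Of the genes that passed at day 3, 98.0% had an effect opposite to their change over time, and of all genes 83.3%. For the day 7 effect the Pearson r was -0.01 and the Spearman rho 0.08. These are 2 relations of the same kind, over contrasts that share the same 12 libraries.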

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

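Of the tests in this part, those of the day 3 pattern (scaling, share of fibre RNA, position on the course) and those of scaling and of vessel share at day 7 were chosen only after the results had been seen. The results listed here stand out because the effect of anti-miR-106b differed between day 3 and day 7 in a direct test, the interaction in limma. The genes were taken from those named above, many of them picked for a small p at day 3 or day 7 in the same libraries. That choice favours a large difference between days, so the genes listed are not independent support for it. Values are the log2 effect at day 7 minus that at day 3.

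In all 3134 genes passed this interaction test, and 15 gene lists passed it in camera with the preset correlation, none of them with an estimated one. List medians were more negative at day 7 for interferon response (-0.94), T and NK cell (-0.96), endothelium (-0.50), macrophage (-0.46), extracellular matrix (-0.41), regenerating fibre (-0.41), mitosis (-0.40), satellite cell (-0.31) and DNA replication (-0.30). They were more positive for mitochondrially encoded (0.94), mature fast fibre (0.69), fatty acid oxidation (0.60), hypoxia and glycolysis (0.59), oxidative phosphorylation (0.55) and dystrophin complex genes (0.44).

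Immune and interferon genes with a more negative effect at day 7 were Isg15 (-1.49), Ifit3 (-1.43), Ifi44 (-1.79), Uba7 (-1.07), H2-T22 (-0.66), Aif1 (-1.02), Arg1 (-3.52), Hmox1 (-0.74), Dok1 (-1.02), Pnp (-0.62) and Npc2 (-0.69). Matrix and tendon genes were Postn (-0.82), Eln (-1.31), Tnc (-0.94), Olfml3 (-0.86), Lrrc15 (-0.55), Ctgf (-0.85) and Scx (-0.73). Endothelial genes were Aplnr (-0.90), Pcdh12 (-0.52), Pecam1 (-0.65), Cdh5 (-0.51), Emcn (-0.77), Tie1 (-0.49) and Eng (-0.89), beside Pcdh1 (-1.09). Genes of myogenic or dividing cells were Myod1 (-0.77), Cdh15 (-0.49), Heyl (-0.72), Mcm7 (-0.38), Tyms (-0.83) and Cdkn1a (-0.56). Ogfr (-0.58), Rnpep (-0.55), Rps10 (-1.47) and Mir6236 (-1.56) had a more negative effect as well. Mir6236 rose with time in the scrambled arm, from 1591 reads over the group at day 3 to 5232 at day 7.

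Muscle and metabolic genes with a more positive effect at day 7, after a negative one at day 3, were Ppp1r3a (1.26), Phkg1 (1.01), Pygm (0.76), Ampd1 (0.58), Ldha (0.84), Ndufs1 (0.72), Uqcrfs1 (0.73), Ppargc1a (0.82), Acsl1 (0.87), Mfn2 (0.71), Vldlr (1.08) and Vegfa (1.05). Mitochondrially encoded ones were mt-Nd5 (1.07), mt-Nd2 (1.21) and mt-Tp (0.83). Dmd (0.66), Dtna (0.55), Cacna2d1 (0.80) and Ano5 (0.81) belong to the membrane of the fibre. The others were Sec14l5 (0.85), Nctc1 (0.80), Carnmt1 (0.92), Pla2g4e (1.099), Exd2 (0.77), Tmtc1 (0.75), Tpbgl (1.01) and the clock gene Ciart (1.57).

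For the lower mature fibre and mitochondrial genes at day 3, the test of the authors' scaling covered the mature fast fibre list only. With reads scaled to library totals its median was still -0.54. That value largely follows from the authors' factors for the arms (means 1.12 and 1.28 for scrambled and anti-miR-106b at day 3). It argues only against these factors as the whole cause for that list. Quantile normalization ended the call of the mitochondrially encoded list. A lower share of fibre RNA alone would raise the markers of other cells alike, but the macrophage list rose above the fibroblast list by 0.54 ± 0.0656 (SE, n = 3), which leaves a change in macrophages open. An earlier position on the course of regeneration stays open: 98.0% of the genes that passed at day 3 went against their own change from day 3 to day 7, as did 83.3% of all tested genes. The test does not decide it, since no value free of the arm difference was at hand. The other 9 splits of the day 3 libraries mix the arms. In them 75.0 to 93.0% of as many genes with the smallest p also lay on 1 side, and 68.4 to 80.6% of all genes. With unequal numbers of the arms on their sides, these splits still hold part of the real difference. Against a straight line through all genes the mitochondrially encoded list lay 0.51 and the mature fast fibre list 0.31 too low (residuals -0.51 and -0.31). Other lists lay about as far off on either side, such as erythrocyte (0.59), tendon (0.44), endothelium (0.32) and inflammatory monocyte genes (-0.38). Macrophage genes were below the line too (-0.22), so their rise was no larger than the line gives. More extensive injury may give the same profile and was not tested, since uninjured muscle is not part of these groups. A biological effect of the inhibitor on the pace of repair is likewise untested.

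The lower endothelial and nerve genes at day 7 are not due to a single library, since without any of the 12 the highest endothelium median was -0.30 and the highest nerve median -0.48. A scaling factor moves all genes of a library alike. Relative to the median of all genes of each library these lists together were lower with the inhibitor (-0.40 ± 0.0818 SE, n = 3), which such a factor would not produce. The lists had been picked by a test against all other genes, so the value largely repeats that call and is no separate support. A lower share of whole vessels would lower pericyte and smooth muscle genes too, but the endothelium list fell below them by 0.29 ± 0.0968 (SE, n = 3; value -0.29). A change in endothelial cells or their transcripts may remain, as a hypothesis. Differences in how much nerve and vessel was taken with the muscle were not tested separately.

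Other splits of the samples were fitted in the same way. The 6 samples of a day or an arm make 10 splits, too few for a share under 0.05. At day 3 the real split gave 5022 genes and the highest other 0, 14 lists against 15 (6 of the 10 splits had as many) and a seed shift of 0.116 in size against 0.0677 (1 of 10). At day 7 they were 9 genes against 224 (3 of 10), 3 lists against 15 (10 of 10) and a seed shift of 0.00481 in size against 0.0665 (10 of 10). The day 7 splits with 224 and 222 genes are those that set scrambled replicate 1 and anti-miR-106b replicate 2 against replicate 3 of both arms, which points to a structure of the samples that the labels do not give. The other 2 splits with scrambled replicate 1 and anti-miR-106b replicate 2 on the same side gave 0 genes each. Day 7 against day 3 gave 9587 genes in the scrambled arm and 11067 in the anti-miR-106b arm, against 0 in the other splits of each (1 of 10), and 17 and 16 lists against 18 and 16 (4 and 3 of 10). The other splits at day 3 mix the arms, and those over time mix the days. They put the real difference into the spread within groups, which lowers their gene counts by construction. Their counts of 0 are thus not values without a difference.

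For the mean of both days and for the change between days, 100 splits were drawn. Chance is not excluded for the mean: 5 of 100 splits gave as many genes as the real 2624 (highest other 5063), 30 as many lists as 14 (19) and 8 as large a seed shift as 0.0605 (0.0879). For the change between days 3 of 100 gave as many genes as 3134 (highest other 4360) and 18 as many lists as 15 (20). These splits also shuffle day 3, and 3 of the 9 that keep its labels reach the real count. Splits that keep those labels hold the whole day 3 difference, so they reach large counts wherever the day 7 effect is small. They thus do not test a change of the effect between days, and chance is not excluded for it. Every split with as many genes kept the real labels of the day 3 libraries (5 of 5 and 3 of 3, while 9 of the 100 splits keep them), and without them the highest counts were 1 and 0. Splits without those labels put the day 3 difference into the spread within groups, which lowers their counts by construction. Both counts thus rest on the day 3 difference.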

How the results depend on the processing

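Total-count and median-of-ratios scaling, voom weights and the removal of 2 day 7 libraries were chosen after the data had been seen. With an estimated correlation between genes 0 lists passed in all 6 comparisons. In contrast, fry passed 10 lists at day 3, 2 at day 7, 5 for the mean of both days and 10 for the change between days. For day 7 against day 3 it passed 28 and 26 in the scrambled and anti-miR-106b arms. Counts of genes at day 3 and in both time comparisons stayed within 1.5 times under all alternatives except library weights at day 3 (8820). Weights ran from 0.291 to 7.86, and also gave 3991 genes for the mean and 5334 for the change between days. Without single libraries the counts ran from 3488 to 5673 genes at day 3, 1457 to 3229 for the mean and 2063 to 4555 for the change between days.

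The 9 genes of day 7 became 59 at an adjusted p under 0.1, 15 with no filter, 20 at 0.5 CPM, 4 at 5 CPM (fewer genes tested), 35 and 46 with 1 and 5 CPM added before the logarithm, 20 with median centring, 17 with quantile normalization, 21 with a robust prior, 58 with library weights and 2 in a fit on the day 7 groups (fewer samples, 799 with an unadjusted p below 0.05). They became 23 with replicate number as a block, 0 with blocks within day in limma (1536 with an unadjusted p below 0.05), 29 with total-count scaling, 22 with median-of-ratios scaling and 542 with 2 day 7 libraries left out, and ranged from 0 without scrambled day 7 replicate 2 (1455 with an unadjusted p below 0.05) to 457 without scrambled day 7 replicate 1. The 3 lists of day 7 became 5 with no filter, 5 with quantile normalization, 8 with weights, 12 with 2 day 7 libraries left out, 10 without scrambled replicate 1, 7 without scrambled replicate 3 and 11 without anti-miR-106b replicate 2, and were 3 without any other library. The causes of these changes were not tested, also where fewer genes or samples were fitted. At day 3 a fit on the compared groups alone raised the count from 5022 to 7386, so fewer samples need not lower it. The main fit used the same spread per gene for both days, while libraries of a group differed more at day 7.

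The seed shift at day 7, near 0, turned positive with shorter sites (0.000363), length-matched genes (0.0150), no filter (0.00916), 0.5 CPM (0.00404), 5 CPM (0.00327), quantile normalization (0.000143), weights (0.0371), voom weights (0.000157) and 2 libraries left out (0.0156). Without single libraries it ran from -0.0225 to 0.0346, positive in 4 of them (0.0142, 0.0116 and 0.000289 the others). At day 3 the shift kept its sign but not its call under total-count scaling (-0.115). For the mean the call was lost at 0.5 CPM (-0.0584), with weights (-0.0522), total-count scaling (-0.0619) and 2 libraries left out (-0.0541), and in 7 of the fits without a library, where the shift ran from -0.0768 to -0.0470. Differences near 0 that turned sign at day 3 were Utrn with quantile normalization (0.00295), weights (0.0215), total-count scaling (0.180), without scrambled replicate 1 (0.0367) and without anti-miR-106b replicate 2 (0.0122; without single libraries from -0.0394 to 0.0367) and Myf5 without scrambled replicate 2 (-0.0237; up to 0.294). At day 7 these were Mcm7 without scrambled replicate 2 (-0.0164; up to 0.119) and Cdkn1a without anti-miR-106b replicate 1 (-0.0108). The cause was not tested.

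Among alternatives of the genes named at day 3, 1897 kept direction and side of the threshold, 31 gained a call, 9 lost it and 6 turned sign, and for its 14 lists 374 kept both and 32 lost the call. At day 7, 478 values of named genes kept both, 34 gained a call and 64 lost it. Calls gained at day 3 were those of E2f1 (13 alternatives), Myh3 (11), Tgfbr2 (5) and Pax7 (2), and at day 7 those of Pecam1 and Cdh5 (11 each), Emcn (4), Prx (3), Ifi44 and Myh3 (2 each) and Tie1 (1). With replicate number as a block, Myh3 at day 3 had an adjusted p of 0.0360, and with blocks within day 0.0183, where the satellite cell list had 0.0520. In the mean of both days Dmd had 0.0515 and 0.0643 with these, and did not pass. Adding 1 or 5 CPM shrinks the folds of genes at low levels by construction, with 5 CPM to 0.40 for Ciart and -0.32 for Rps10 at day 7. A level of 1 CPM is 28.1 to 46.9 reads. No alternative varied depth, so what depth limits was not tested.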

Other observations

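The test in this part, on 3′ UTR length, was set before its result had been seen. Several gene groups beyond those described moved with time. In the scrambled arm dystrophin complex genes rose from day 3 to day 7 (9 of 13 higher and 2 lower, median 0.53, camera adjusted p = 0.0130), as did hypoxia and glycolysis genes (10 of 14 higher and 3 lower, 0.71, 0.0127) and mitochondrially encoded genes (7 of 9 higher, 0.67, 0.0104). Myoblast and early differentiation genes fell (11 of 14 lower and 2 higher, -0.82, 0.0204), as did inflammatory monocyte genes (13 of 14 lower and 1 higher, -2.83, 3.95e-04), satellite cell genes (7 of 11 lower, -0.46, 0.0412) and atrophy and denervation genes (8 of 13 lower and 3 higher, -0.48, 0.0486). With an estimated correlation none of the 7 lists passed (adjusted p = 0.375 to 0.484). In the anti-miR-106b arm T and NK cell genes fell as well (9 of 10 lower, -2.18, camera adjusted p = 0.0306, and an adjusted p of 0.604 with an estimated correlation). In the mean of both days Schwann cell and nerve genes were lower with anti-miR-106b (3 of 7 lower, 4 over the list alone, -0.42, camera adjusted p = 0.0114, and 0.559 as the adjusted p with an estimated correlation).

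The day 7 libraries differed among themselves within both arms. The mean level of mitosis genes was 0.75, 1.05 and 1.77 log2 CPM in scrambled replicates 1, 2 and 3 and 1.59, 0.65 and 1.48 in anti-miR-106b replicates 1, 2 and 3. Macrophage genes were at 3.79, 4.19 and 4.40 in the former and 4.55, 3.81 and 4.49 in the latter, and embryonic and neonatal fibre genes at 4.92, 5.22 and 5.79 and at 5.62, 5.07 and 5.64. Endothelial genes did not overlap between the arms, with 5.10, 5.02 and 4.90 against 4.75, 4.63 and 4.68, nor did Schwann cell and nerve genes, with 2.34, 2.07 and 2.12 against 1.49, 1.55 and 1.82. In 6 libraries of a day an exact two-sided permutation test of 3 against 3 cannot give less than 0.1. Principal component 1 of the day 7 libraries alone held 32.5% of their variance, with scrambled replicates at -23.4, 8.37 and 28.5 and anti-miR-106b replicates at -3.27, -15.6 and 5.39, so it does not follow the arms. In the day 3 libraries alone it held 71.9% and separated them.

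Genes with a match to the miR-106b seed were not higher at day 3, as they could be if losing the microRNA raised target transcripts. Longer 3′ UTRs could hide such a rise, since genes with a site have longer ones. Against genes without a site matched on UTR length the shift was -0.0709, below 0, which argues against a rise hidden by UTR length. Shuffled sites, without matching on length, had a median shift of -0.0890 at day 3. The matched shift was not set against shuffled sites, so a small rise within the wider day 3 difference stays open. An effect on translation alone, or in a minority of cells, was not tested and stays open.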
